A study of Mus musculus with 6 samples.

How the data were processed

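Splenic B cells of BALB/c mice were profiled on Affymetrix mouse expression arrays, 3 from infected and 3 from uninfected mice. Per the labels' protocols, mice were infected orally with 5 cysticercoids, CD19-positive cells were isolated magnetically on day 7 and sorted, and biotin-labelled RNA was prepared with a 3' in vitro transcription kit from RNA of high integrity. A description field of the labels gives hours in place of days; the titles and protocols, which give days, were followed. Groups and replicate numbers were taken from the sample titles.

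The deposited values were 1 level per probe set and array, read here as log2 expression from their range of 1.99 to 14.8, since the authors' scale is not given in the sources used here. Background correction, summarization and normalization by the authors are likewise not given in the sources used here. No detection calls were used, so the trpn control probe sets, which read a bacterial gene, stand for background.

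Of 45101 probe sets, 64 control probe sets were left out of the tests. The platform annotation used here listed 35890 probe sets: 34945 had exactly 1 gene symbol, 932 had several and 9160 were not listed. Symbols of 34754 probe sets, whether or not they changed, were taken through their Entrez identifiers from a RefSeq gene table of assembly GRCm38.p6, used for names only. As no genome build is named, no coordinates are given. Each gene was represented by the probe set with the highest mean over the 6 arrays among those with exactly 1 symbol, which gave 18193 genes, 9010 of them with more than 1 probe set. No filter on dim genes was applied.

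The rule fixed before the data were examined was to keep deposited values unless array medians or quartiles differed by more than 0.1 log2. Medians differed by 0.0425, lower quartiles by 0.164 and upper quartiles by 0.151, so the arrays were quantile normalized. The lower quartile averaged 5.49 in uninfected and 5.39 in infected and the upper quartile 8.80 and 8.90, so quantile normalization removed a difference in spread that followed the groups.

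Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no replicate block), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The 38 gene lists, fixed before the data were examined, were tested with limma camera (preset correlation 0.01, two-sided, at least 3 measured members), adjusted over the lists. Each list is also given as its number of members past 0.05 over all genes and adjusted over the list alone. Values of control probe sets were compared with two-sided exact permutation tests, whose smallest possible p with 3 against 3 arrays is 0.1.

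Genes were named by a rule fixed before the data were examined. It took the 12 largest rises and 12 largest falls among called genes whose infected arrays all lay on 1 side of the uninfected arrays. It added up to 4 members of each list past 0.05 adjusted over the list alone, or, where none passed, the 2 with the largest moderated statistic, and a fixed panel of regulatory B cell genes. Genes outside the rule are said to have been chosen after their values were seen.

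Alternatives were centring on array medians, filters on dim genes, the mean of all probe sets of a gene, an intensity trend with a robust prior, array weights, the replicate block, leaving out each array, all probe sets in place of genes, unmoderated least squares, other thresholds, camera with an estimated correlation, and fry. Deposited values as they stand, scaling to 14 hybridization control probe sets, and the macrophage list without C1qb were added after seeing the data. The fit was tested on simulated data in 5 runs over 18193 genes with 200 changed genes each: it recovered 51.8% of changes of 0.5 log2, 90.8% of changes of 1 and 99.7% of changes of 2, and 4.48% of its calls were false. In the data 1684 genes were called, so the simulated setting differs and these shares need not hold for the real calls.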

Results

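Splenic B cells were compared between BALB/c mice given 5 cysticercoids (larvae) of the rat tapeworm Hymenolepis diminuta by mouth and uninfected mice, with cells taken on day 7. CD19-positive cells had been selected magnetically and then sorted, and each of the 6 samples was read on 1 Affymetrix mouse expression array, 3 infected and 3 uninfected. The array medians lay between 7.03 and 7.07 on the log2 scale, and 18193 genes were tested. The comparison asks which transcripts differ in splenic B cells during the infection, in a study whose title concerns the effect of such cells on colitis. The number of arrays limits the precision, and as nothing states that the samples came from separate animals, the p-values measure the spread between these samples, which may be technical. The trpn control probe sets, which read a bacterial gene, gave 3.15 to 5.14. Means inside that range cannot be separated from background, and where 1 group lay inside it the difference is given as at least the other mean minus 5.14. All changes below are log2 differences, infected minus uninfected, with the SE of the limma fit (n = 3 arrays per group) unless SD is stated.

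Sorted B cell samples from infected mice gave more signal for the actin-bundling protein gene Pls3, the calcium-binding protein gene S100a6 and the complement gene C1qb than those from uninfected mice. Pls3 rose by 2.68 ± 0.27, or 6.41-fold, from 5.71 ± 0.67 (SD) to 8.39 ± 0.03 (SD), with an adjusted p of 0.00618. S100a6 rose by 2.12 ± 0.10, or 4.34-fold, with the lowest adjusted p of the named genes, 0.000157. C1qb rose by 1.59 ± 0.20, or 3.02-fold (adjusted p = 0.00897), while its 2 other probe sets were higher 2.83-fold and 1.29-fold, the second short of the threshold. In total 1684 genes differed, 1141 higher and 543 lower in infected (67.8% higher). The counts depended on the scaling, with 2171 higher and 528 lower after median centring (80.4%), 1921 and 743 on deposited values, and 5027 and 41 with scaling to the hybridization controls (99.2%). Without uninfected replicate 2 they were 96 and 27. With all arrays, 4961 genes had an unadjusted p under 0.05. The 3 infected arrays lay wholly above or below the 3 uninfected arrays for 32.6% of genes, where chance gives 10%. Most differences were small: 16 genes were higher and 1 was lower by at least 1 log2 unit, and the median fold was 1.36 among genes called higher and 1.32 among genes called lower.

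The other large rises belonged to genes of varied function. Tmem267 rose by 1.39 ± 0.15. Rgs13, a regulator of G-protein signalling known from germinal centre B cells, also passed, but no size is given. Its uninfected mean of 3.94 lay inside the trpn range and its infected mean of 5.24 just above it, with infected replicate 1 (4.85) inside. Acss2, which makes acetyl-CoA from acetate, rose by 1.15 ± 0.21 (0.61 and 0.32 in its other probe sets). Anxa1, which encodes the phospholipid-binding protein annexin A1, rose by 1.11 ± 0.09 (0.45 in its other probe set). Lmo7 rose by 1.10 ± 0.10 (0.17 in its other probe set), Ddx25 by 1.09 ± 0.12, Spaca1 by 1.08 ± 0.18, the bile acid receptor gene Nr1h4 by 1.08 ± 0.09 and the phospholipase gene Pla2g7 by 1.05 ± 0.15. Adjusted p-values of these genes ran from 0.00421 to 0.0164.

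**Figure D1:**
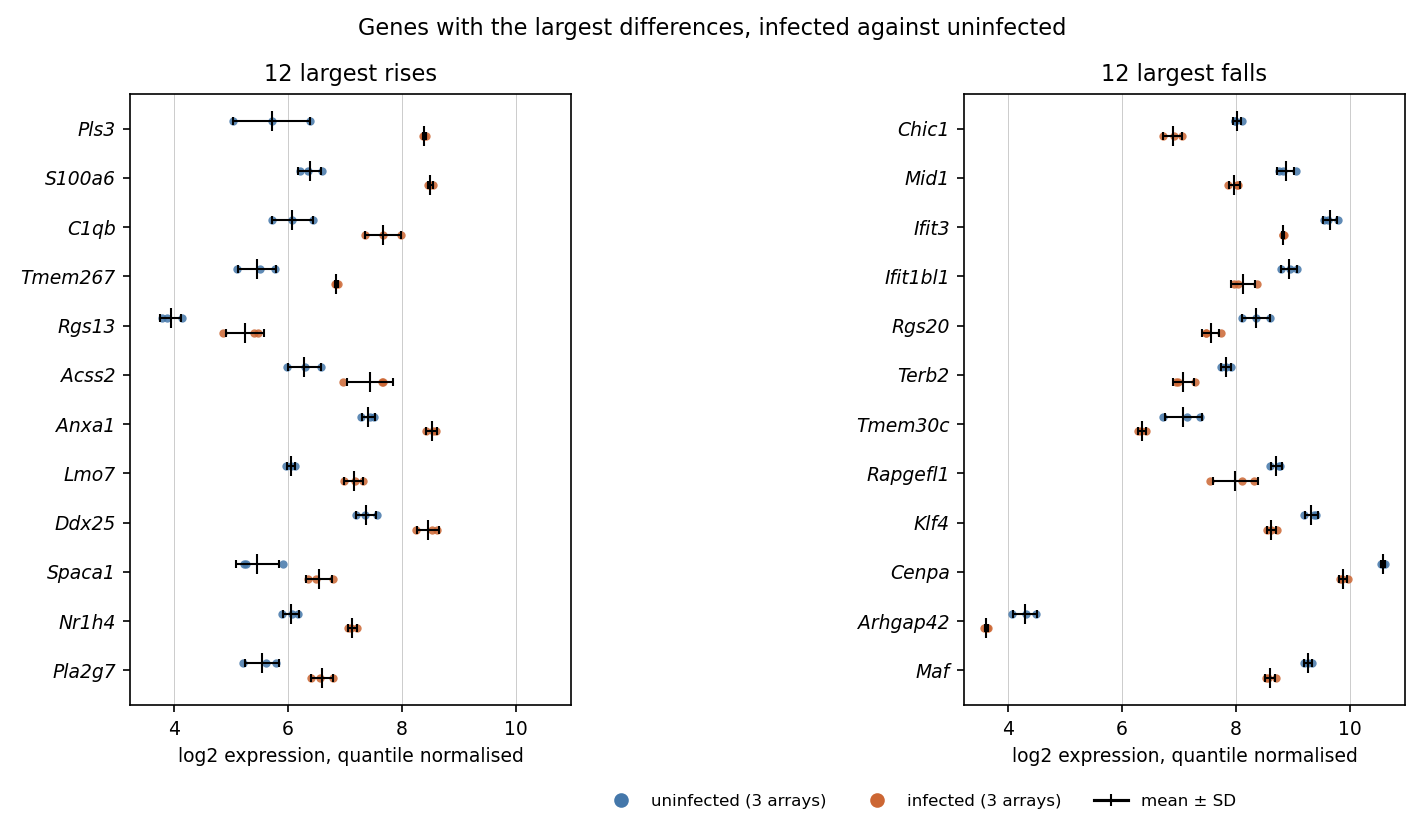
Log2 expression (x axis, quantile normalised) of the 12 genes with the largest rise and the 12 with the largest fall in infected; points are single arrays, 3 uninfected and 3 infected, and the black marks give the mean and SD. For each gene the 3 infected arrays lie on 1 side of the 3 uninfected arrays, from Pls3 (5.71 against 8.39) to Maf (9.27 against 8.60).

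Falls were smaller and included interferon-induced and transcription factor genes. Chic1 fell by 1.13 ± 0.10, or 2.19-fold (adjusted p = 0.00421), and its other 2 probe sets gave -0.86 and -0.92. Mid1 fell by 0.90 ± 0.10 (-0.25 and -0.20 in its other probe sets), and the interferon-induced genes Ifit3 and Ifit1bl1 fell by 0.82 ± 0.08 and 0.81 ± 0.12. Rgs20 fell by 0.79 ± 0.13, Terb2 by 0.76 ± 0.10, Tmem30c by 0.73 ± 0.15 and Rapgefl1 by 0.72 ± 0.17. Other probe sets of Rgs20 were at -0.00 and -0.11, and those of Tmem30c at 0.30 and -0.03. The transcription factor gene Klf4 and the centromere histone gene Cenpa both fell by 0.70, with SEs of 0.09 and 0.07. Other probe sets of Cenpa were at -0.34 and -0.24. The transcription factor gene Maf fell by 0.67 ± 0.08. Arhgap42 also passed, but both its means (4.29 and 3.62) lay inside the trpn range, so no size is given. One of the 5 other probe sets of Maf went the opposite way, at 0.12. Adjusted p-values of these 12 genes ran from 0.00421 to 0.0355.

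Genes of the mitochondrial respiratory chain formed the most strongly shifted of the 38 gene lists. Of 32 measured members, 22 were higher and 1 was lower in infected over all genes, and 26 and 1 when adjusted over the list alone; the median difference was 0.39. Ndufa4 rose by 0.62 ± 0.07, Cox5a by 0.59 ± 0.08, Ndufa6 by 0.66 ± 0.10 and Uqcrq by 0.68 ± 0.12, whereas Cox7c, a further subunit of the chain named after its value was seen, fell by 0.52 ± 0.09. Of the 3 other probe sets of Uqcrq, 1 was higher, at 0.16, and the others were at -0.03 and -0.36. The list was shifted up by limma camera with a preset correlation (adjusted p = 2.4e-14; adjusted p = 0.282 with an estimated correlation).

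Lists of other growth and metabolic genes were also shifted up by camera. In the glycolysis list 4 of 14 members were higher over all genes and 5 when adjusted over the list alone (median 0.16; adjusted p = 0.00792; adjusted p = 0.282 with an estimated correlation). Pgk1 rose by 0.63 ± 0.08, Tpi1 by 0.54 ± 0.08, Ldha by 0.42 ± 0.07 and Aldoa by 0.34 ± 0.07, with 1 of the 4 other probe sets of Aldoa at -0.16. In the cholesterol synthesis list 3 of 15 members were higher, and 3 when adjusted over the list alone (median 0.17; adjusted p = 0.0106; adjusted p = 0.44 with an estimated correlation). These were Sqle, which rose by 0.73 ± 0.09, Fdps by 0.65 ± 0.11 and Msmo1 by 0.63 ± 0.13, while the second probe sets of Fdps and Msmo1 were at -0.04 and -0.18. Among ribosomal protein genes 6 of 31 were higher, and 8 when adjusted over the list alone (median 0.11; adjusted p = 0.00168; adjusted p = 0.282 with an estimated correlation). In a split made after seeing the data, 4 of 15 large subunit members were higher (median 0.20). For these, camera gave an adjusted p of 6.6e-06, and of 0.0634 with an estimated correlation. Of the small subunit members 2 of 16 were higher (median -0.0069, camera adjusted p = 0.243, tested as up despite the negative median). Rpl14 rose by 1.04 ± 0.11, Rps6 by 0.86 ± 0.21 (0.07 in its other probe set), Rps19 by 0.44 ± 0.07 and Rpl7 by 0.38 ± 0.08. The infected means of Rpl14 (8.82) and Rps6 (7.61) lay far under the median level of the list, 13.26. Rpl37, named after its values were seen, is counted as higher in the list and the large subunit. Both its means (4.78 and 5.10) lay inside the trpn range, so it cannot be separated from background. In the heat shock list 1 of 14 members, the mitochondrial chaperonin gene Hspe1, rose (0.50 ± 0.07), and Bag3, with both means (4.46 and 4.83) inside the trpn range, passed only when adjusted over the list alone, as 1 of 2 members (list median 0.10; adjusted p = 0.0234; adjusted p = 0.44 with an estimated correlation). In the upper 50% of genes by level the cholesterol synthesis and heat shock calls were lost (adjusted p = 0.171 for each). The heat shock call was also lost in the upper 75% (adjusted p = 0.0606) and without uninfected replicate 3 (adjusted p = 0.0911).

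Cell cycle genes were shifted up by camera, and so were B cell activation, plasma cell and B1 B cell genes, whose calls were lost in further settings. Of 32 measured cell cycle genes 5 were higher over all genes and 6 when adjusted over the list alone (median 0.20; adjusted p = 0.000206; adjusted p = 0.282 with an estimated correlation). The ribonucleotide reductase gene Rrm2 rose by 0.86 ± 0.17, Nusap1 by 0.70 ± 0.15 and the replication helicase gene Mcm6 by 0.69 ± 0.10. Bub1, with both means (4.31 and 4.93) inside the trpn range, passed only over the list alone. Of 20 B cell activation genes 6 were higher over all genes, and 7 were higher and 1 lower when adjusted over the list alone (median 0.08; adjusted p = 0.0394; adjusted p = 0.282 with an estimated correlation). Batf rose by 0.65 ± 0.10, Traf1 by 0.61 ± 0.08, Ccnd2 by 0.50 ± 0.10 and Nfkb2 by 0.42 ± 0.07; the other probe set of Nfkb2 was at -0.04. The B cell activation call was lost in the upper 50% and 75% of genes by level (adjusted p = 0.171 and 0.0606) and with the replicate block (adjusted p = 0.0546). It was also lost without infected replicate 2, uninfected replicate 1 or uninfected replicate 3 (adjusted p = 0.0654, 0.0738 and 0.0517), and its median was 0.041 without infected replicate 3. The plasma cell list had 2 of 18 members higher over all genes and 7 when adjusted over the list alone (median 0.20; adjusted p = 0.0182; adjusted p = 0.415 with an estimated correlation). Ell2 rose by 0.51 ± 0.09 and Mzb1 by 0.44 ± 0.09. Ssr4 at 0.40 ± 0.11 and Fkbp11 at 0.39 ± 0.12 passed only over the list alone. Other probe sets of Ssr4 were at -0.19 and -0.12, and those of Fkbp11 at -0.02 and 0.03. The plasma cell call was lost with the mean of all probe sets of a gene (adjusted p = 0.112) and in the upper 50% of genes (adjusted p = 0.252), and its median was 0.11 without infected replicate 1. In the B1 B cell list 2 of 13 members were higher, S100a6 and the scramblase gene Plscr1 (0.51 ± 0.12), and 3 when adjusted over the list alone, with Anxa2 at 0.38 ± 0.11 (median 0.14; adjusted p = 0.0239; adjusted p = 0.44 with an estimated correlation). This call was lost with the mean of all probe sets (adjusted p = 0.0807), in the upper 50% and 75% of genes (adjusted p = 0.146 and 0.0606) and without uninfected replicate 2 (median 0.053; adjusted p = 0.122). With S100a6 at 2.12 the mean of the B1 B cell list was 0.29, above its median, and the list was not tested without that gene.

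Immediate early and type I interferon genes were shifted down by camera on quantile-normalized values. Of 23 immediate early genes, which respond within minutes to stimulation, 5 were lower over all genes and 6 when adjusted over the list alone (median -0.16; adjusted p = 0.00792; adjusted p = 0.282 with an estimated correlation). Besides Klf4, Nr4a1 fell by 0.58 ± 0.09, Fosb by 0.53 ± 0.08 and Nr4a3 by 0.44 ± 0.10, with other probe sets of Nr4a3 at -0.16 and 0.27. Of 27 type I interferon genes 4 were lower over all genes, and 4 were lower and 2 higher when adjusted over the list alone (median -0.10; adjusted p = 0.0234; adjusted p = 0.282 with an estimated correlation). Besides Ifit3, Ifit1 fell by 0.65 ± 0.12, the nucleic acid sensor gene Zbp1 by 0.47 ± 0.07 and Oas2 by 0.46 ± 0.07. The type I interferon call was lost with the mean of all probe sets (adjusted p = 0.075) and without uninfected replicate 3 (adjusted p = 0.1). The transitional B cell list had 2 of 12 members lower, and 2 when adjusted over the list alone (median -0.13; adjusted p = 0.033; adjusted p = 0.282 with an estimated correlation). These were the transcription factor gene Myb, which fell by 0.46 ± 0.08, and Cd93, which fell by 0.35 ± 0.07. Its call was lost with the mean of all probe sets (adjusted p = 0.0755) and without infected replicate 2, uninfected replicate 1 or uninfected replicate 3 (adjusted p = 0.0544, 0.0616 and 0.1). In the B cell identity list 0 of 16 members passed the limma test over all genes or adjusted over the list alone, and 5 had an unadjusted p under 0.05. Its median was -0.09 (adjusted p = 0.0498; adjusted p = 0.282 with an estimated correlation), with Ebf1 at -0.26 ± 0.07 and Ly6d at 0.29 ± 0.08. The B cell identity list was called in 0 of the 6 fits without 1 array (adjusted p between 0.0615 and 0.11). It was not called with array weights (adjusted p = 0.0562), with the replicate block (adjusted p = 0.0815) or in the upper 75% of genes (adjusted p = 0.0582). These 4 lists were not called on deposited values without quantile normalization (adjusted p between 0.162 and 0.862). With arrays scaled to the hybridization controls, which put the median of all genes at 0.19, their medians were 0.15, 0.13, 0.13 and 0.19, none above that of all genes.

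**Figure D2:**
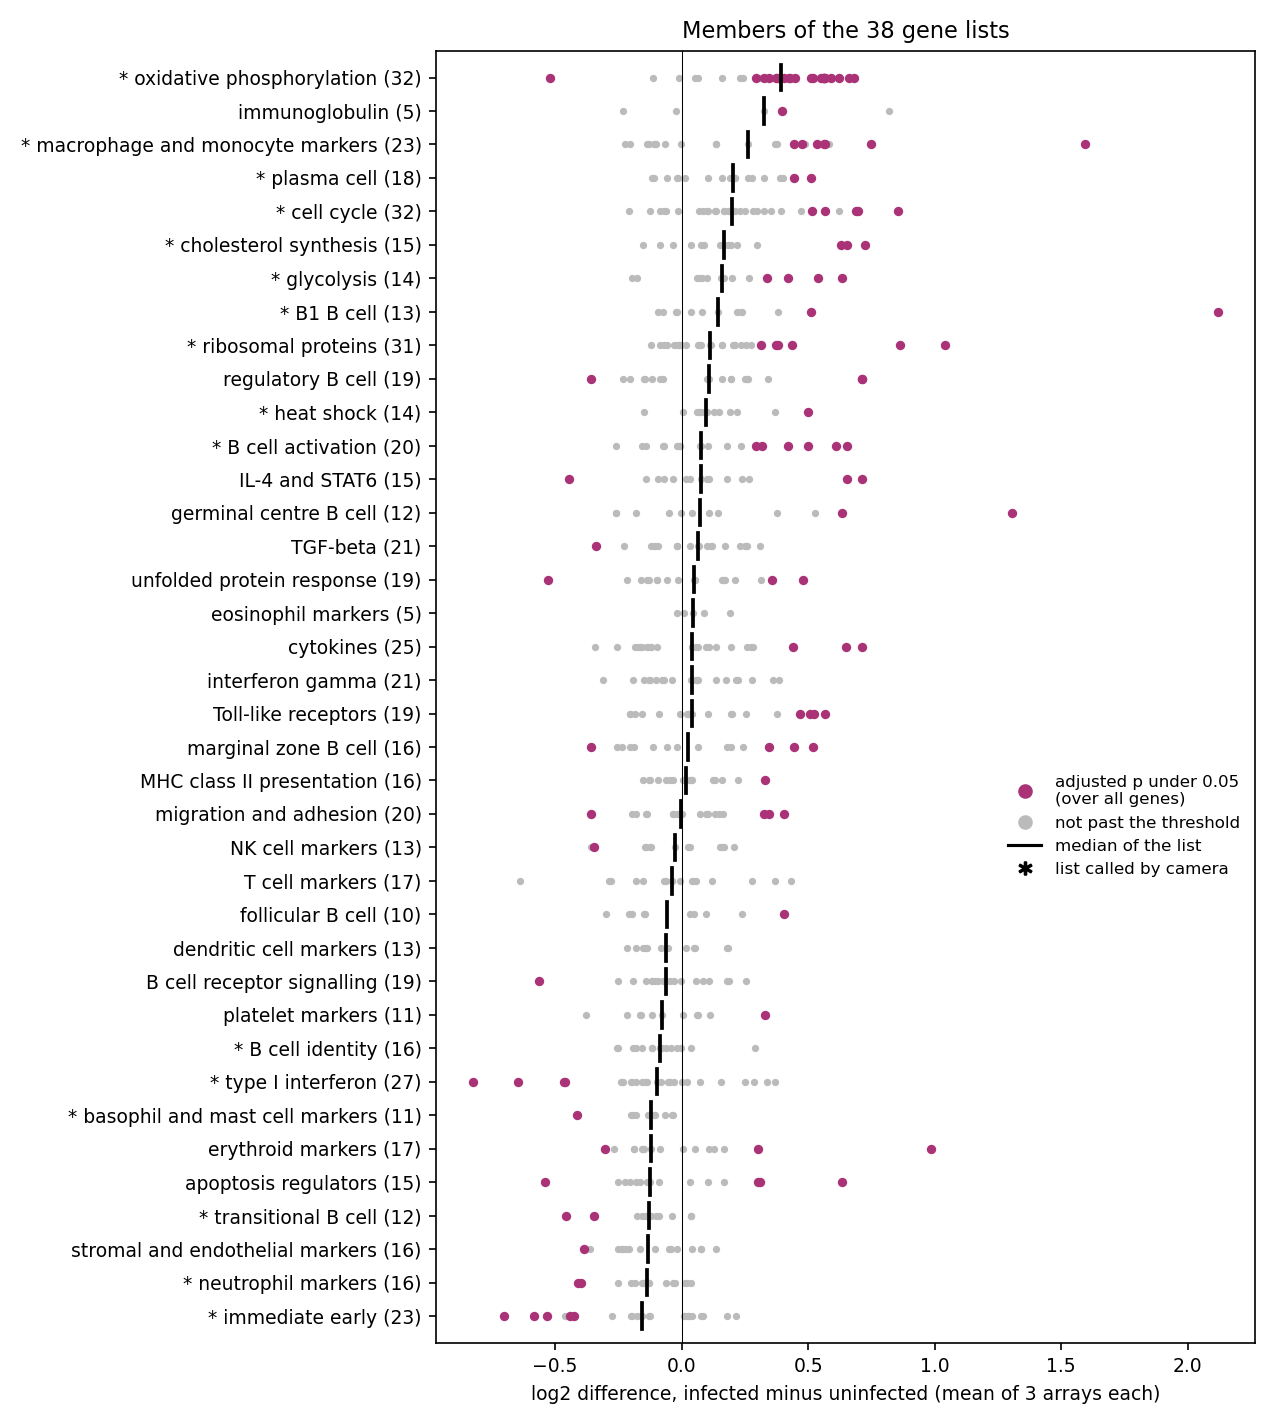
Log2 difference, infected minus uninfected (x axis), of each measured member of the 38 gene lists, ordered by median, with 3 arrays per group; each point is a gene, coloured where its adjusted p over all genes was under 0.05, the black bar is the list median, an asterisk marks lists called by camera with a preset correlation, and the bracket gives the members measured. Oxidative phosphorylation has the highest median (0.39) and immediate early the lowest (-0.16), and none of the lists was called with an estimated correlation.

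Genes linked to regulatory B cells went both ways, and the list as a whole was not shifted. Ebi3, a subunit of the cytokines IL-27 and IL-35, rose by 0.71 ± 0.12 (adjusted p = 0.015), and Pdcd1lg2, which encodes the inhibitory ligand PD-L2, by 0.71 ± 0.13. Cd1d1, the lipid-presenting molecule used to mark some regulatory and marginal zone B cells, fell by 0.36 ± 0.07 (adjusted p = 0.0237), and its other probe set was at -0.47. Cd9, at 0.34 ± 0.11, passed only over the list alone. Of 19 members 2 were higher and 1 lower over all genes, and 6 and 2 when adjusted over the list alone (median 0.11; camera adjusted p = 0.432). Il10 did not pass (adjusted p = 0.269), and its means of 4.22 and 4.42 lay inside the trpn range. Tgfb1 was at 0.26 ± 0.08 (adjusted p = 0.0793), Prdm1 at 0.26 ± 0.09 (adjusted p = 0.0991), Il4ra at 0.24 ± 0.07 (adjusted p = 0.0705), Xbp1 at 0.16 ± 0.08, Il12a at 0.11 ± 0.08 and Havcr1 at 0.10 ± 0.11. Fcer2a was at 0.03 ± 0.08, Cr2 at -0.06 ± 0.08, Cd80 at -0.07 ± 0.10, Cd5 at -0.08 ± 0.14, Ms4a1 at -0.08 ± 0.07, Cd86 at -0.14 ± 0.08 and Cd274 at -0.15 ± 0.07, none past the threshold. Il6 did not pass either (adjusted p = 0.476), with both means (2.90 and 2.78) below the trpn range. Cd19, Aicda, Ighg1 and Ighe were not analysed here, as the annotation used gives no probe set to them alone.

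Camera called none of the lists of other B cell subsets and antibody genes. Fry, which tests whether a list's own genes move 1 way without comparing them with other genes, called the immunoglobulin list up (adjusted p = 0.0102). Of 16 marginal zone genes 3 were higher and 1 lower over all genes, and 4 and 3 when adjusted over the list alone (camera adjusted p = 0.582). Plac8 rose by 0.52 ± 0.07, and the sphingosine-1-phosphate receptor gene S1pr3 by 0.35 ± 0.08. Of 10 follicular genes 1 was higher, the chemokine receptor gene Cxcr5 (0.40 ± 0.08), while 2 were higher and 2 lower when adjusted over the list alone, with Bach2 at -0.30 ± 0.09 and Foxp1 at -0.21 ± 0.07 (camera adjusted p = 0.693). Of 12 germinal centre genes 2 were higher, Rgs13 and the death receptor gene Fas (0.63 ± 0.15), and 2 were higher and 1 lower when adjusted over the list alone, with Neil1 at -0.26 ± 0.08 (camera adjusted p = 0.432). Of 5 immunoglobulin genes Ighg3 rose by 0.40 ± 0.08; 3 were higher and 1 lower when adjusted over the list alone, with Igha at 0.82 ± 0.23, Jchain at 0.32 ± 0.10 and Ighm at -0.23 ± 0.07 (camera adjusted p = 0.301). Ighm was lower in 3 of its 10 other probe sets.

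Camera called none of the remaining signalling lists. Fry called Toll-like receptor genes and MHC class II genes up (fry adjusted p = 0.0463 and 0.0343). Of 19 Toll-like receptor genes 4 were higher over all genes and 6 when adjusted over the list alone (camera adjusted p = 0.0744). Tlr3 rose by 0.57 ± 0.14, Ly96 by 0.52 ± 0.12, Tlr4 by 0.51 ± 0.08 and the adaptor gene Myd88 by 0.47 ± 0.09. Other probe sets of Tlr4 were at 0.07, -0.31 and 0.38. Of 25 cytokine genes 3 were higher, and 6 when adjusted over the list alone (camera adjusted p = 0.565); besides Ebi3, Ifng rose by 0.65 ± 0.13 and Ltb by 0.44 ± 0.10, and Tnf was at 0.28 ± 0.09. Of 15 IL-4 and STAT6 genes 2 were higher and 1 lower, and 3 and 1 when adjusted over the list alone (camera adjusted p = 0.316), with Gfi1, which fell by 0.44 ± 0.10. Of 19 unfolded protein response genes 2 were higher and 1 lower, and 3 and 1 when adjusted over the list alone (camera adjusted p = 0.701). Sdf2l1 rose by 0.48 ± 0.09 and Pdia4 by 0.36 ± 0.08, Dnajb9 fell by 0.53 ± 0.08, and Manf was at 0.32 ± 0.10. Of 19 B cell receptor signalling genes 1 was lower, and 1 when adjusted over the list alone, Malt1, which fell by 0.56 ± 0.11 (camera adjusted p = 0.432). Of 20 migration and adhesion genes 3 were higher and 1 lower, and 3 and 1 when adjusted over the list alone (camera adjusted p = 0.565). Gpr183 rose by 0.32 ± 0.07, with its other probe set at -0.00, and Cxcr3 fell by 0.36 ± 0.09. The median of that list was -0.00 and its mean 0.03, so that median and test differed in sign. Of 15 apoptosis regulators 3 were higher and 1 lower, and 3 and 1 when adjusted over the list alone (camera adjusted p = 0.565). Bid rose by 0.31 ± 0.07 and Ccng1 by 0.30 ± 0.07, and Pmaip1 fell by 0.54 ± 0.09. Of 21 TGF-beta genes 1 was lower, and 1 when adjusted over the list alone, Skil, which fell by 0.34 ± 0.07 with its other probe set at 0.18 (camera adjusted p = 0.442). Of 16 MHC class II genes 1 was higher, and 1 when adjusted over the list alone, H2-Oa, which rose by 0.33 ± 0.08 (camera adjusted p = 0.693). Of 21 interferon gamma genes 0 passed limma over all genes or adjusted over the list alone and 6 had an unadjusted p under 0.05 (camera adjusted p = 0.582), with Tbx21 at 0.38 ± 0.10 and Gbp3 at 0.36 ± 0.11.

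Markers of macrophages, a cell type outside the CD19 gate, were shifted up alongside these changes. Of 23 macrophage and monocyte markers 7 were higher over all genes and 9 when adjusted over the list alone (median 0.26; adjusted p = 0.011; adjusted p = 0.282 with an estimated correlation). Besides C1qb, the heme oxygenase gene Hmox1 rose by 0.75 ± 0.12 and the red pulp macrophage factor gene Spic by 0.57 ± 0.11, and Ifitm3, at 0.58 ± 0.19, passed only over the list alone. The list was not called on deposited values without quantile normalization (adjusted p = 0.0924) or centred on each array's median (adjusted p = 0.1). Its median was 0.16 to 0.17 without uninfected replicate 2 or 3 or infected replicate 1. Neutrophil markers were shifted down by camera, with 2 of 16 lower, and 2 when adjusted over the list alone (median -0.14; adjusted p = 0.0234; adjusted p = 0.282 with an estimated correlation): Csf3r fell by 0.41 ± 0.08, and Mmp8 passed with both means (4.37 and 3.97) inside the trpn range. The neutrophil call was lost with an intensity trend (adjusted p = 0.055), in the upper 75% of genes (adjusted p = 0.107) and without infected replicate 3 (adjusted p = 0.068), and its median was -0.085 without uninfected replicate 2. Basophil and mast cell markers were shifted down by camera, with 1 of 11 lower, and 1 when adjusted over the list alone, Gata2, which fell by 0.41 ± 0.09 with its other probe set at 0.21 (median -0.12; adjusted p = 0.0498; adjusted p = 0.415 with an estimated correlation; fry adjusted p = 0.0839). Of the 11 markers 6 had both means no higher than the trpn range, as did 5 of the 16 neutrophil markers, and such genes cannot be separated from background. The basophil call was lost without infected replicate 2 or 3 or uninfected replicate 1 or 2 (adjusted p between 0.0562 and 0.132), and its median was -0.23 without infected replicate 1. It was also lost with an intensity trend (adjusted p = 0.0945), with the mean of all probe sets (adjusted p = 0.112) and in the upper 75% of genes (adjusted p = 0.136).

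**Figure D3:**
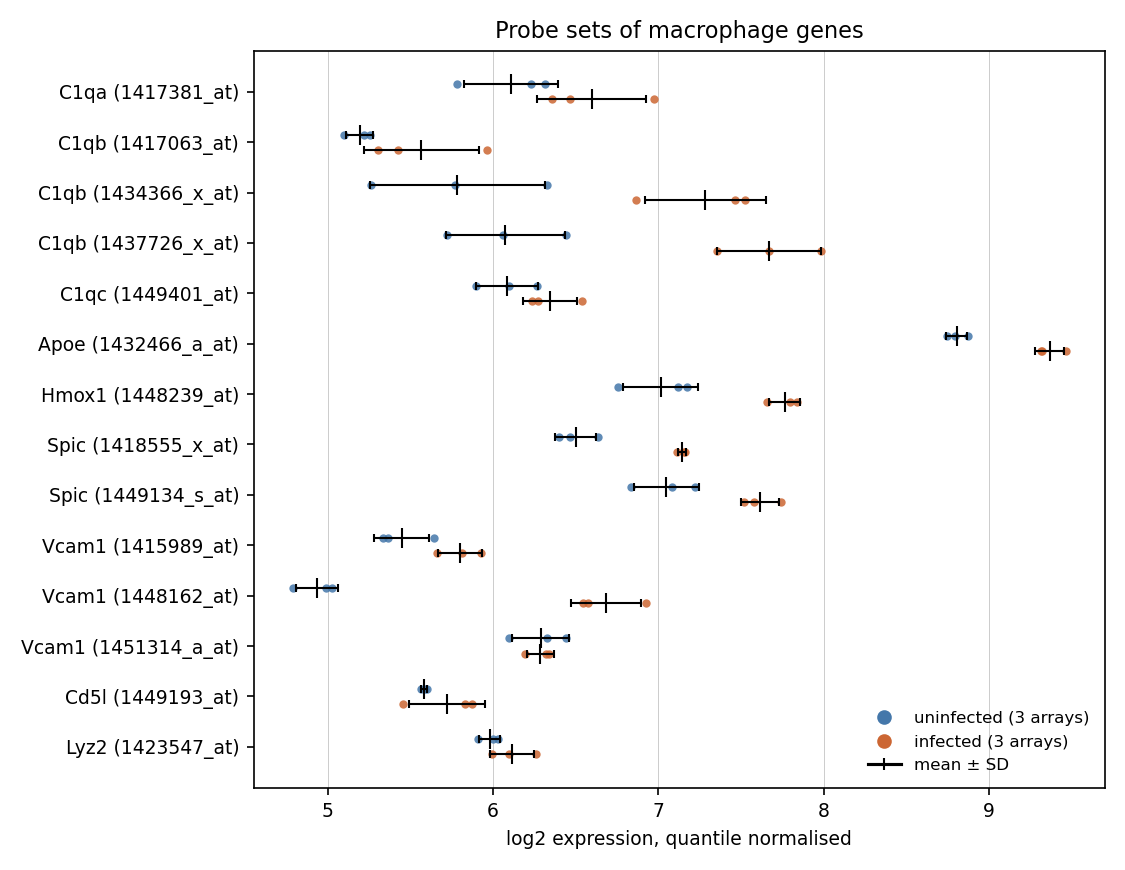
Log2 expression (x axis, quantile normalised) of each probe set of 9 macrophage genes, chosen after their values were seen; points are single arrays, 3 uninfected and 3 infected, and the black marks give the mean and SD. The brightest and the dimmest probe set of C1qb differ by 1.59 and 0.37 between the groups. The brightest of Vcam1 differs by -0.00, another is higher by at least 1.54, from 4.93 inside the trpn range to 6.68, and the other is at 0.35.

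Other non-B-cell lists were called by neither camera nor fry, and 5 of 13 natural killer cell, 4 of 11 platelet, 4 of 17 erythroid and 2 of 5 eosinophil markers had both means no higher than the trpn range. Of 17 T cell markers 0 passed limma over all genes or adjusted over the list alone and 4 had an unadjusted p under 0.05 (camera adjusted p = 0.701), with Cd3e at 0.43 ± 0.12 and Cd3g at 0.37 ± 0.11. Of 13 natural killer cell markers 1 was lower, and 1 when adjusted over the list alone, Eomes, which fell by at least 0.16, from 5.30 to 4.95, inside the trpn range (camera adjusted p = 0.592). Of 13 dendritic cell markers 0 passed limma over all genes or adjusted over the list alone and 1 had an unadjusted p under 0.05 (camera adjusted p = 0.582), with Batf3 at -0.21 ± 0.09 and Ccl17 at 0.18 ± 0.08. Of 5 eosinophil markers 0 passed limma over all genes, adjusted over the list alone or at an unadjusted p under 0.05 (camera adjusted p = 0.649), with Prg2 at 0.19 ± 0.13. The means of Siglecf, 3.21 and 3.30, lay inside the trpn range. Of 17 erythroid markers 2 were higher and 1 lower, and 2 and 2 when adjusted over the list alone (camera adjusted p = 0.534). Hemgn rose by 0.99 ± 0.18 and Car2 by 0.30 ± 0.08, Tfrc fell by 0.30 ± 0.07, and Slc4a1 was at -0.31 ± 0.09. With scaling to the hybridization controls Tfrc was at 0.01, below the median of 0.19 that this scaling gives all genes. Of 11 platelet markers 1 was higher, and 1 when adjusted over the list alone, Itgb3, which rose by 0.33 ± 0.08 (camera adjusted p = 0.604). Of 16 stromal and endothelial markers 1 was lower, and 1 when adjusted over the list alone, Col1a2, which fell by 0.38 ± 0.10 (camera adjusted p = 0.062). Other probe sets of Col1a2 were at -0.10 and 0.01.

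Camera called 16 of the 38 lists with a preset correlation, 10 up and 6 down, and 0 with an estimated correlation, where 4 had an unadjusted p under 0.05; fry called 18. Without uninfected replicate 2 limma called 123 genes, including 24 of the 95 named genes called with all arrays, and without uninfected replicate 1 or infected replicates 1, 2 or 3 it called 576, 534, 591 and 849.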

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

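The tests of array scaling, RNA degradation, macrophage RNA, C1qb probe sets and repeat RNA were chosen after the results they bear on had been seen; the tests of probe set brightness, single probe sets and other splits were set before.

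Among probe sets without a single gene symbol, which the gene tests leave out, 443 of 10092 passed the threshold, 164 higher and 279 lower, a share of 4.39% against 5.33% of probe sets with a single symbol. The Gapdh control probe sets, also outside the gene tests, were higher in infected by 0.48 on deposited values (exact permutation p = 0.1, the smallest possible), while the beta-actin control probe sets differed by 0.0037 (exact permutation p = 0.5).

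The rise of oxidative phosphorylation genes was weighed against 3 technical explanations. The list median exceeded that of all genes by 0.40 after quantile normalization and by 0.51 on deposited values, which argues against that normalization as the whole cause; median centring and control scaling shift all genes of an array alike and test nothing here. Brightness is argued against too: of 10000 lists matched on mean level 0 had a median as high as 0.39, and the central 95% of these medians ended at 0.0843. RNA degradation in infected samples would raise 3' over 5' signal. The 3' minus 5' signal differed by 0.0571 ± 0.016 (SE) for the beta-actin controls (exact permutation p = 0.1, the smallest possible). For the Gapdh controls it differed by -0.12 ± 0.12 (exact permutation p = 0.4). These controls went opposite ways, so they show no shared rise of 3' over 5' signal, though the small beta-actin rise stays. An effect of the infection on respiratory chain transcripts is a candidate explanation, as a hypothesis only, since the call was lost with an estimated correlation (adjusted p = 0.282) and a change in the mix of B cell subsets was not tested.

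C1qb and other macrophage markers were higher, and macrophage RNA in the sorted cells was weighed as a source, although the CD19 selection and the sort would remove macrophages. C1qa and C1qc, made with C1qb in the same cells, differed by 0.37 on average. This is 0.42 ± 0.15 (SE) under the 0.80 that 50% of the C1qb rise would give. The shortfall cannot decide on macrophage RNA, since the mark was set on the brightest C1qb probe set and another C1qb probe set also missed it. Probe sets that read other transcripts may add to the C1qb rise, since the lowest of the 3 C1qb probe sets was at 0.37. Its levels of 5.19 and 5.57 lay close to the trpn range. For the other markers macrophage RNA stays open as well. The list without C1qb was still shifted (median 0.20, camera adjusted p = 0.0239). The 7 abundant macrophage genes had a median of 0.26, with 6 above 0 but only Apoe and Hmox1 past the threshold. The probe sets of Vcam1 disagreed (-0.0017 in the brightest, at least 1.54 higher and 0.35 in the others). Of the 23 markers 2 stood on another list and 2 lay above the median level of all genes in uninfected B cells, and expression by B cells themselves stays open.

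The falls in infected were weighed against signal of single probe sets and against less repeat-containing RNA. Other probe sets of genes called lower were also lower in 74.97% of cases (557 of 743, exact 95% interval 71.7% to 78.0%), against 49.5% for genes not called. The bound of 75% set beforehand lies inside the interval, so the explanation cannot be told apart for part of the falls. For genes called higher the share also higher was close, at 77.9% (776 of 996, exact 95% interval 75.2% to 80.5%). Fewer passed the threshold themselves in the same direction: 89 of the 743 for genes called lower and 227 of the 996 for genes called higher. Both intervals treat probe sets as independent, though they share the arrays. The control probe sets for B1 and B2 repeats differed by -0.28 (exact permutation p = 0.1, the smallest possible), and relative to the hybridization controls they differed by -0.0765 (exact permutation p = 0.3), which leaves this open as well. An effect of the infection stays among the open explanations.

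The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 1684 genes and 16 lists, and was the only 1 of the 10 splits to give as many of either; the highest of the other splits gave 0 genes and 6 lists.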

How the results depend on the processing

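Scaling to the hybridization controls, deposited values as they stand and the list without C1qb were chosen after seeing the data; quantile normalization, planned as an alternative, became the main setting. The direction of all 95 called named genes was kept in every leave-one-out. This could not fail, as for each of them the infected arrays all lay on 1 side of the uninfected arrays. Of these genes 7 were called under every alternative. Against 1684 genes (1141 higher, 543 lower, 67.8% higher), median centring called 2699 (2171 higher, 80.4%) and deposited values 2664 (1921 higher). Scaling to the hybridization controls, which puts the median of all genes at 0.19, called 5068 (5027 higher, 41 lower, 99.2%). The upper 50% of genes by level gave 2601 (948 lower) and 8 lists, and the upper 75% gave 10 lists, with fewer genes tested. An intensity trend with a robust prior gave 2902 (1833 and 1069), all probe sets 880 lower, unmoderated least squares 124 (73 and 51), at least 1 log2 unit 17 (16 and 1), and unadjusted p with 1.5-fold 257 (228 and 29). An estimated correlation called 0 lists, against 18 by fry. Leaving out 1 array gave 123 to 1325 genes, 96 to 862 higher, 27 to 463 lower and 12 to 15 lists, lowest for genes without uninfected replicate 2; fewer arrays lower the power. Whether replicate numbers pair the arrays stays open. Correlations of same-numbered deviations were 0.140, 0.0113 and 0.0879, against -0.15 to 0.0771 for other pairs. Uninfected replicates 1 and 3 correlated best with the infected replicate of the same number, and uninfected replicate 2 with infected replicate 1 (0.0152). The replicate block gave 1551 genes (1086 and 465) and 14 lists, without B cell activation (camera adjusted p = 0.0546) and B cell identity (camera adjusted p = 0.0815). For dim genes such as Il10, inside the range of the trpn controls, background limits what a difference shows. Of the 1684 genes, 13 turned with the mean of probe sets. Turns with control scaling follow from its shift of all genes and are no evidence on a gene (32 genes, among those named here only Tfrc, at 0.013). The other named genes that turned were not called. With median centring these were Cr2 0.049 and Ms4a1 0.0033, and on deposited values Cr2 0.023. With control scaling they were Ebf1 0.053, Foxp1 0.084, Bach2 0.0092, Neil1 0.057, Ighm 0.067, Cr2 0.23, Cd80 0.088, Cd5 0.10, Ms4a1 0.18, Il6 0.041, Cd86 0.16 and Cd274 0.16. With the mean of probe sets they were Ighm 0.19 and Cd80 0.16. Over the leave-one-outs they were Cd5 -0.20 to 0.078, Siglecf -0.027 to 0.187, Fcer2a -0.0080 to 0.063 and Cd80 -0.16 to 0.0086.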

Other observations

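The gene families below were found by a screen of 116 symbol families with at least 15 members, run after the data had been seen. Genes of the mitochondrial ribosome were higher together: 20 of 47 Mrpl genes and 11 of 29 Mrps genes passed the threshold and 0 were lower by limma, with medians of 0.34 and 0.28 (camera adjusted p = 2.0e-15 and 2.5e-11). Mrpl35 rose by 0.69 ± 0.08 and Mrps14 by 0.59 ± 0.08. Genes for import into mitochondria followed, with 8 of 15 Timm genes higher (median 0.36; camera adjusted p = 2.1e-05) and Timm13 at 0.67 ± 0.08. RNA polymerase subunits (7 of 25 Polr genes; adjusted p = 9.4e-05) and translation initiation factors (7 of 47 Eif genes; adjusted p = 0.000606) were also shifted up, with Polr2d at 0.59 ± 0.08 and Eif3m at 0.59 ± 0.07. All these families were also up on deposited values, and none was called with an estimated correlation (adjusted p = 0.745 with an estimated correlation for each).

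Relatives of the most raised genes were chosen after their values were seen. Of these, 4 of 12 S100a, 3 of 11 Anxa and 3 of 18 Serpinb genes were higher and 0 were lower, with medians of 0.085, 0.11 and 0.024. Over all genes 1141 of 18193 were higher. The screen did not call the Serpinb family (camera adjusted p = 0.547), and it did not test the S100a and Anxa families, which have under 15 members. S100a4 rose by at least 0.51, from 4.98 inside the range of the trpn controls, and S100a13 by 0.43 ± 0.07 beside S100a6, and Anxa5 by 0.49 ± 0.12 and Anxa7 by 0.31 ± 0.07 beside Anxa1. The protease inhibitor genes Serpinb9 and Serpinb6b rose by 1.00 ± 0.14 and 0.95 ± 0.16. Of 21 regulators of G-protein signalling 2 were higher and 3 lower: Rgs10 rose by 0.52 ± 0.12 beside Rgs13, and Rgs1 fell by 0.56 ± 0.08 and Rgs2 by 0.36 ± 0.07 beside Rgs20. Vcam1, which the gene test read as flat by its brightest probe set, had another probe set that rose by at least 1.54, from 4.93, inside the range of the trpn controls, to 6.68 (adjusted p = 0.00481 over all probe sets). A further probe set was at 0.35 ± 0.11.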
